A study of Homo sapiens with 60 samples.

How the data were processed

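The deposited table holds expected counts per Ensembl gene. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.3a to the human genome (GRCh38) and counted with RSEM 1.3.3. The annotation release, the program settings and the strand are not given in the sources used here. No reads were aligned here. The table has 60675 genes and 60 libraries; 71.9% of the nonzero values have no decimal part, since estimated counts of multi-mapped reads are fractional, and all were rounded before testing.

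Symbols come from a separate table of gene names, which holds 56558 of the gene IDs, and from GENCODE v29 where that table gives none. Positions come from GENCODE v29. Genes without a symbol hold 0.52% of the counts. Genes were kept by edgeR's filterByExpr by group with a minimum count of 10, which left 16644. Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model with robust dispersion for 57 replicated libraries in 19 groups (common dispersion 0.00345). Each p-value is from edgeR's quasi-likelihood F test, adjusted by Benjamini-Hochberg over the genes tested, and a gene is called under 0.05. The standard error of a log2 fold change is its absolute value over the square root of F. CPM are counts scaled to the TMM-adjusted library total, with standard deviations over 3 libraries.

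The comparisons are each of 3 doses against vehicle and 500 against 20 µg/mL for 6 extracts, and 2 interaction contrasts between a formula and its constituent herb. Gene lists were tested with camera of limma on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 180 tests of 1 kind of comparison. Of 31 lists 30 had at least 4 expressed members. They cover AHR, NRF2, PXR and CAR, ATF4, p53, and YAP and actin targets; ER chaperones, heat shock proteins, immediate early, NF-kB, interferon-stimulated and acute phase genes; cholesterol and fatty acid synthesis, fatty acid oxidation, glycolysis, hypoxia, gluconeogenesis and bile acid genes; secreted liver proteins, metallothioneins, lysosome and autophagy, G2 and mitosis, DNA replication, nuclear oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins, histones, and fibroblast, leukocyte, lung and neural markers. The number called over the list alone uses Benjamini-Hochberg over its members.

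Named genes had a symbol, an adjusted p under 0.05, a mean of at least 5 CPM in either group and all 3 extract libraries on the same side of the 3 vehicle libraries. The largest fold changes in each direction were taken. In each passing list the 3 called members of largest absolute log2 fold change were named with no CPM minimum, so some, such as FOS, HK1, IRS2 and ALDH3A1, lie below 5 CPM in both groups. CYP1A1, HMOX1, CYP3A4 and ALB are given in any case. Some genes that the rule names are not reported here. Genes that share sequence or overlap another gene, such as single metallothioneins, HSPA1A and HSPA1B, carry counts that depend on how shared reads were assigned. For Soshiho-tang the 9405 genes with a symbol and at least 10 CPM in at least 1 of 2 libraries were ranked by the log2 ratio of 500 over 20 µg/mL. List medians were placed among 10000 random lists matched on expression. Each random member was drawn from the 16644 tested genes, within 50 expression ranks of the list member.

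The groups, tests, lists, naming rules and most alternatives were set before the data were examined. The alternatives are RLE scaling, no filter, DESeq2, a fit with only the groups compared, a replicate block, a replicate block within the first code number, leaving out each library, an estimated inter-gene correlation, and for correlations a mean of at least 10 CPM. Pseudocount and mean filter alternatives for normalized values do not apply to counts. The library classes, the class as covariate, the fits within 1 class and the interaction contrasts were chosen after the data were seen.

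Library totals run from 20446542 to 32386486 counts. At the lowest and highest total a floor of 3 counts equals 0.147 and 0.0926 CPM, and this floor covers counting error only. Replicates correlated at 0.988 to 0.993 in log2 CPM, a measure that hides most differences between replicates. The chi-square of counts per degree of freedom, which measures spread beyond counting error, ran from 2.268 to 19.49 over replicate pairs. In vehicle it was 17.31 and 14.19 for the pairs with replicate 1, and 3.214 for replicates 2 and 3. The analysis was tested on simulated data, with 67, 67 and 66 genes raised or lowered 1.5, 2 and 4-fold. They were recovered at 97.0, 100 and 100% in the layout of Menthae Herba 500 µg/mL against vehicle with 21 false calls. In the layout of Soyo-san 500 against 20 µg/mL they were recovered at 95.5, 100 and 100% with 5 false calls. Genes varied independently of each other in the simulation, so it holds no library classes within a group.

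The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The sample labels give 0.1% DMSO for vehicle and the design text 2%, and the amount in the groups with water extracts is not given in the sources used here, so a comparison with vehicle holds any difference in DMSO. Treatments named in the study design without libraries in this series, wortmannin among them, are not analysed here.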

Results

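The series holds 60 RNA-seq libraries of HepG2, a hepatocellular carcinoma cell line, treated for 24 h with water extracts of herbs and formulas used in Korean medicine. Vehicle (n = 3) is compared with Menthae Herba, Saposhnikoviae Radix, Saengmaek-san, Guibi-tang, Soyo-san and Okbyeongpung-san, each at 500, 100 and 20 µg/mL with 3 libraries per dose. Soshiho-tang has 1 library at each of the 3 doses. The labels do not say that replicates are separate cultures, so the p-values measure only the spread between these samples. Library totals run from 20446542 to 32386486 expected counts with a median of 25862356. The comparison with vehicle asks which genes an extract changed, and that of 500 with 20 µg/mL asks for a change with dose within 1 extract.

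CYP1A1 and AKR1B10 are the 2 genes higher at 500 than at 20 µg/mL in all 6 replicated extracts. CYP1A1 (chr15 74719542 to 74725610, GENCODE v29 on GRCh38) encodes a cytochrome P450 induced through the aryl hydrocarbon receptor (AHR). Its log2 fold change at 500 against vehicle ran from 0.68 ± 0.08 with Saengmaek-san to 3.66 ± 0.07 with Soyo-san, where the mean rose from 7.75 ± 0.71 to 98.1 ± 0.84 CPM (n = 3 and 3, ± SE for fold changes and ± SD for CPM). AKR1B10 (chr7 134527592 to 134541408), an aldo-keto reductase under NRF2 control, rose by 0.53 with Okbyeongpung-san and by 1.52 with Menthae Herba. Metallothionein mRNAs, which encode zinc-binding proteins, were lower at 500 than at 20 µg/mL in each of the 6 extracts by the list test, though with Okbyeongpung-san 0 of the 8 genes of the list were called (4 alone) and the summed CPM changed by -0.353 ± 0.228 in log2. The CPM summed over 7 metallothionein genes was 439 ± 13.9 in vehicle, and at 500 µg/mL it ran from 79.4 ± 4.67 with Menthae Herba to 312 ± 22.8 with Okbyeongpung-san.

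**Figure D1:**
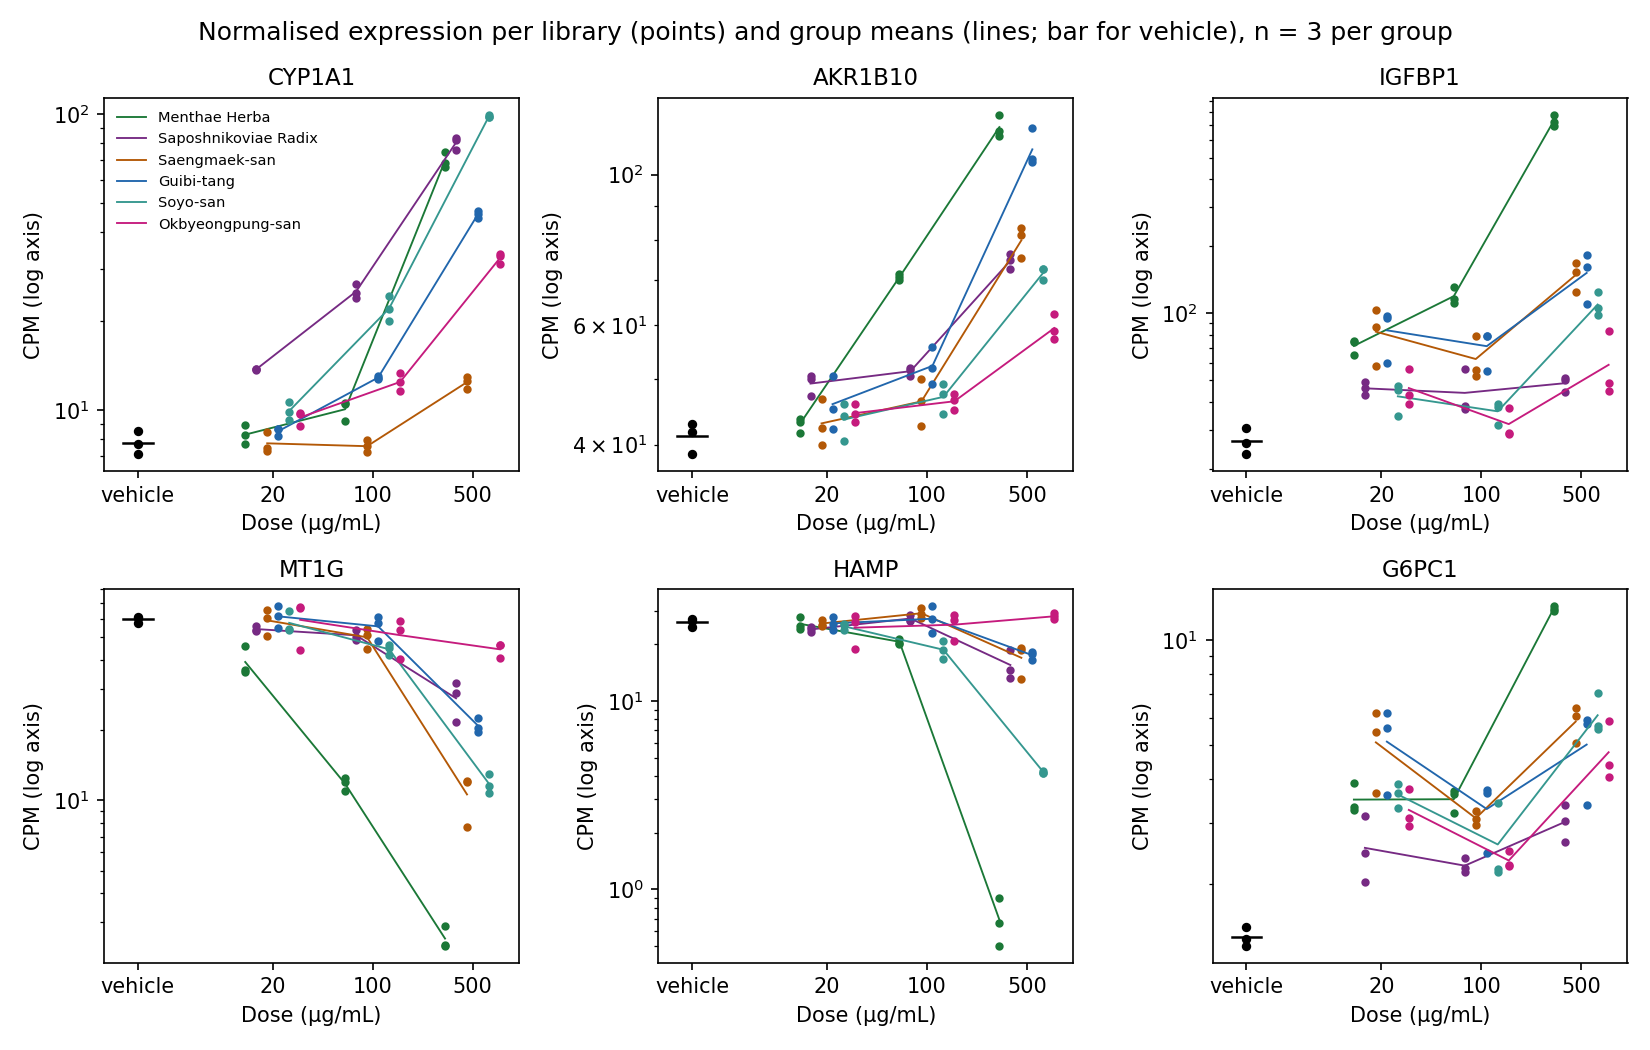
CPM on a log axis against dose in µg/mL for CYP1A1, AKR1B10, IGFBP1, MT1G, HAMP and G6PC1; each point is 1 library, coloured by extract, with vehicle (n = 3) at the left. CYP1A1 stood at 7.75 CPM in vehicle and 98.1 CPM with Soyo-san at 500 µg/mL.

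At 500 µg/mL Menthae Herba changed 6623 genes against vehicle, Soyo-san 3581, Guibi-tang 2232 and Saengmaek-san 2105, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05 over 16644 genes. The genes G6PC1 (glucose-6-phosphatase, chr17 42900797 to 42913369) and NQO1 (a quinone reductase, chr16 69706996 to 69726951) rose with all 6 extracts. G6PC1 was already higher than vehicle at 20 µg/mL in all 6, by a mean log2 fold change of 1.4. From 20 to 500 µg/mL its mean change was 0.59. A difference of the vehicle libraries from all extract libraries could enter any comparison with vehicle. Glycolysis genes passed the list test with every extract, and the call for Saposhnikoviae Radix was lost at adjusted p = 0.0567 with an estimated correlation.

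**Figure D2:**
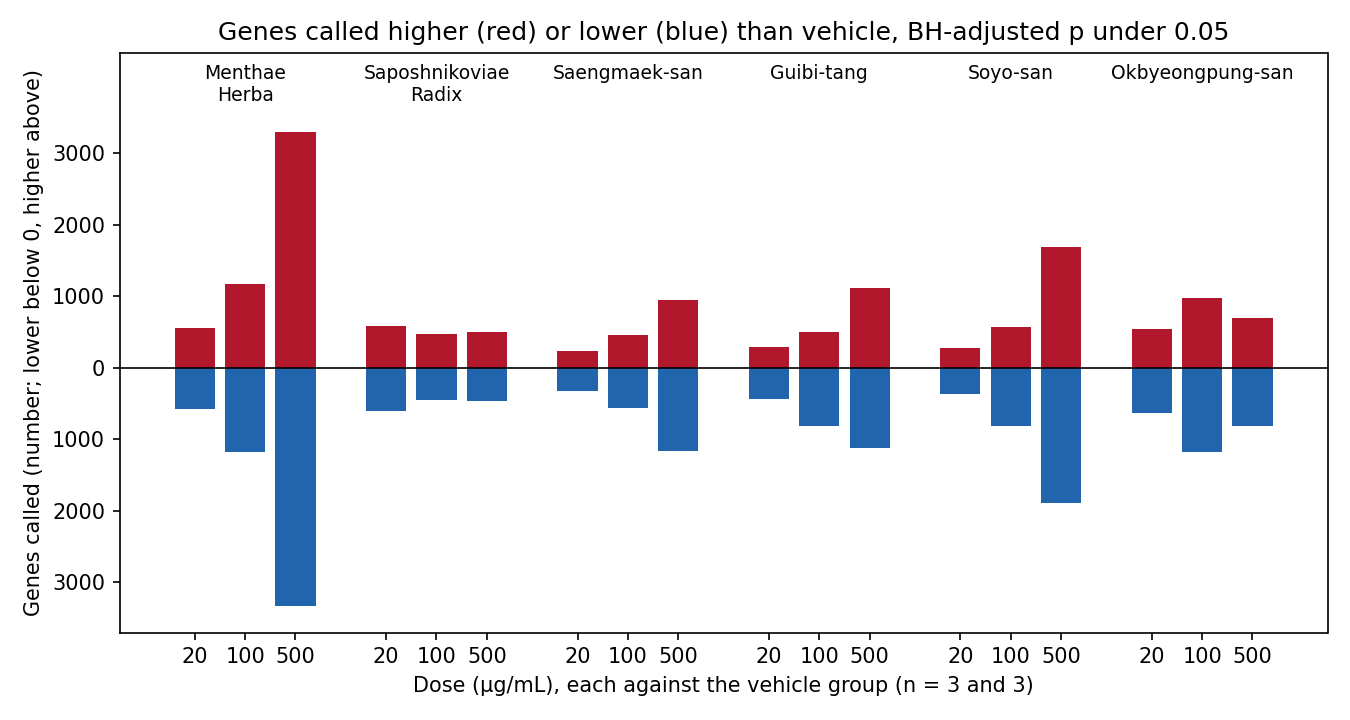
Number of genes called higher (above 0) or lower (below 0) than vehicle at adjusted p under 0.05, for 6 extracts at 20, 100 and 500 µg/mL, n = 3 and 3 per bar. Menthae Herba at 500 µg/mL had 3291 higher and 3332 lower genes.

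**Figure D3:**
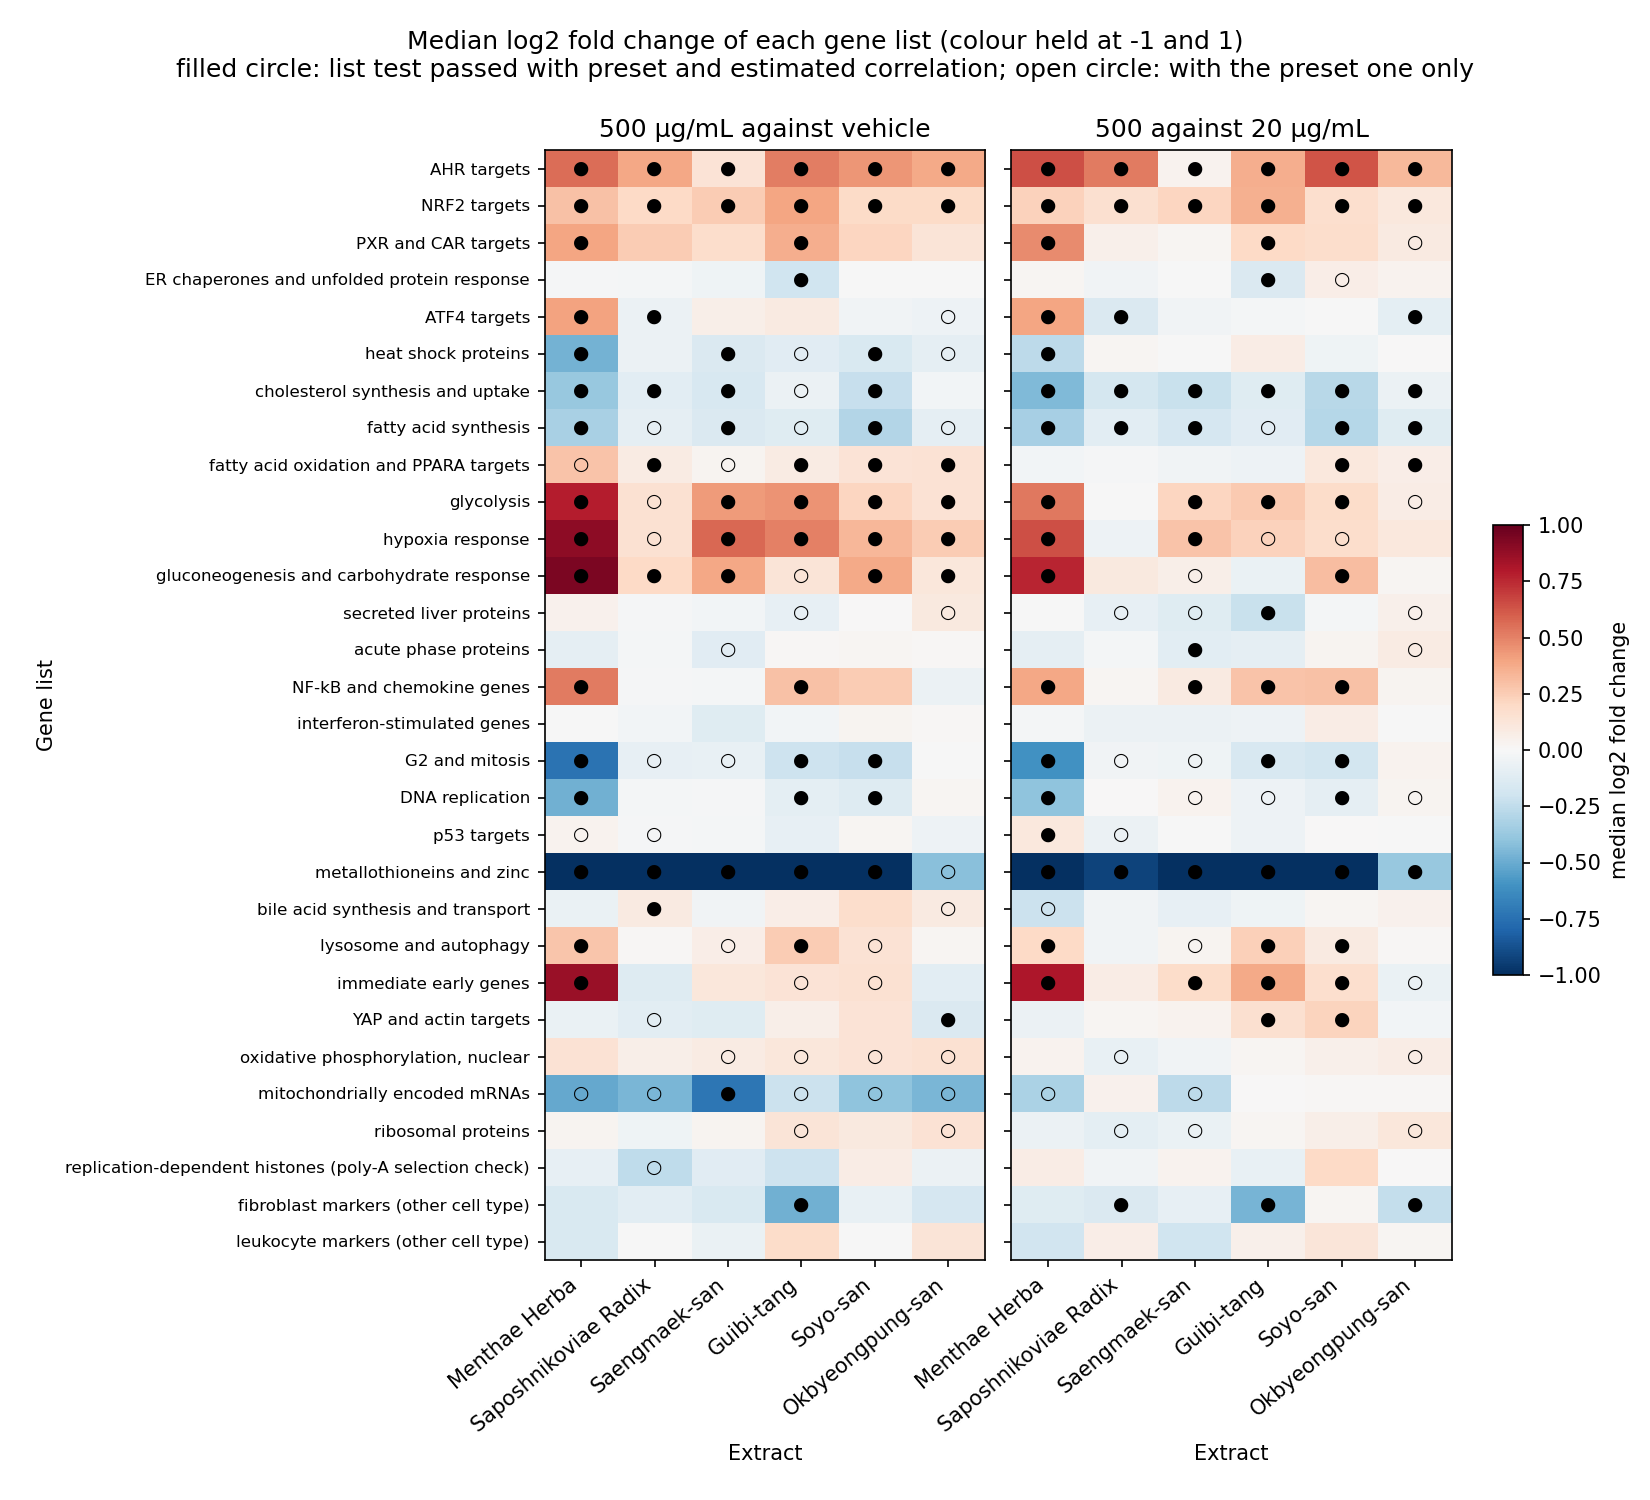
Median log2 fold change of 30 fixed gene lists (vertical axis) in 6 extracts (horizontal axis), 500 µg/mL against vehicle at the left and against 20 µg/mL at the right. Filled circles passed the list test with the preset and the estimated correlation, open circles with the preset correlation only; the metallothionein median with Menthae Herba was -3.257 against vehicle.

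The nuclear noncoding RNA MALAT1 separates the libraries into 2 classes, with 31 libraries at 175 to 283 CPM and 29 at 387 to 553 CPM. KCNQ1OT1, another nuclear noncoding RNA, ran from 120 to 167 CPM in the lower class and from 206 to 329 CPM in the higher one. All vehicle, Menthae Herba and Saposhnikoviae Radix libraries lie in the lower class and all Soyo-san, Okbyeongpung-san and Soshiho-tang libraries in the higher one. Saengmaek-san has 2 lower and 1 higher library at each dose; Guibi-tang has 2 and 1 at 500 and 1 and 2 at 100 and 20 µg/mL. Both RNAs were chosen after their values were seen. For Soyo-san and Okbyeongpung-san the difference from vehicle therefore holds the class difference, while 500 against 20 µg/mL lies within 1 class.

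**Figure D4:**
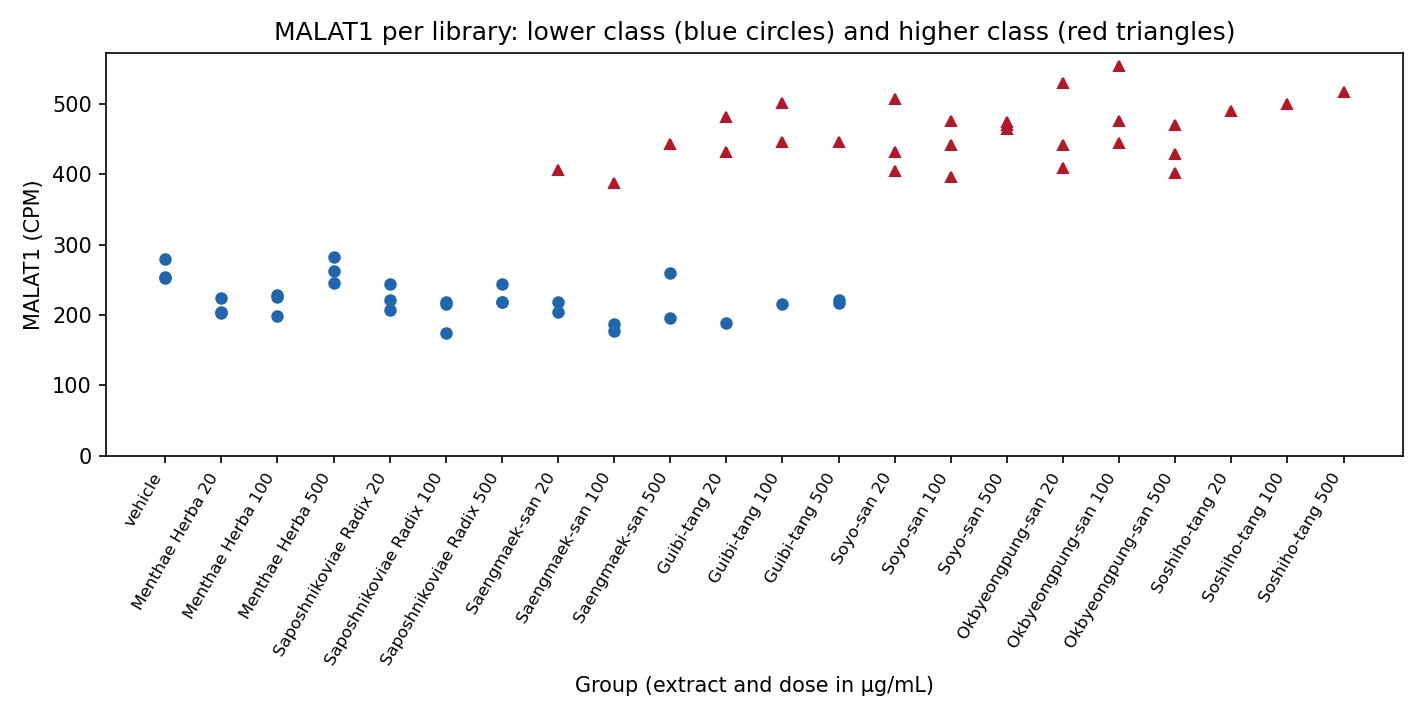
MALAT1 level in CPM by group (extract and dose in µg/mL), each point 1 of 60 libraries. Blue circles mark the lower class and red triangles the higher class. MALAT1 lies at 175 to 283 CPM in the lower class and 387 to 553 CPM in the higher class.

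Menthae Herba, the mint herb, at 500 µg/mL raised IGFBP1, an insulin-like growth factor binding protein, by 4.78 ± 0.25 log2 units (adjusted p = 4.1e-19), from 26.5 ± 3.65 to 728 ± 41.3 CPM (chr7 45888357 to 45893668). The carbonic anhydrase CA9, a hypoxia target, rose by 3.63 ± 0.47, CYP1A1 by 3.16 ± 0.07 and G6PC1 by 3.12 ± 0.20. HAMP, which encodes the iron hormone hepcidin (chr19 35280716 to 35285143), changed by -5.20 ± 0.21 (adjusted p = 2e-24) to 0.689 CPM, and MT1G (chr16 56666731 to 56668065) by -4.54 ± 0.20. Of the 6623 genes called (n = 3 and 3), 3291 rose and 3332 fell, 617 of them at least 2-fold.

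With Menthae Herba at 500 µg/mL 19 of 20 glycolysis genes rose (adjusted p of the list = 7.91e-20, 19 over the list alone), among them HK1 by 1.72 and PFKFB3 by 1.38, and 18 of 19 hypoxia genes (1.94e-15, 18 alone), among them NDRG1 by 1.86. In the gluconeogenesis list 9 of 13 rose (1.43e-06, 10 alone), with IRS2 at 1.88. Of 13 mitochondrially encoded mRNAs 9 fell (0.00166, 13 alone, with MT-ND3 -0.64), a list call lost at adjusted p = 0.392 with an estimated correlation; the mitochondrial share was 13.015 to 16.418% in vehicle and 11.779 to 14.274% with 20 µg/mL. Of 21 ATF4 targets 15 were higher and 2 lower (1.97e-06, 16 and 2 alone, with DDIT4 1.82, ATF3 1.39), 13 of 16 immediate early genes higher (4.75e-10, 13 alone, with FOS 2.36, EGR1 1.81), and 16 higher and 2 lower of 21 lysosome and autophagy genes (5.85e-06, 16 and 2 alone, with GABARAPL1 1.08). NRF2 targets had 16 higher and 4 lower of 26 (6.57e-06, 18 and 5 alone, with SLC7A11 1.48), AHR targets 3 higher and 1 lower of 6 (0.00515), and NF-kB and chemokine genes 8 higher and 1 lower of 12 (0.00307, with CXCL8 1.16, BIRC3 1.01).

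Proliferation genes fell with Menthae Herba at 500 µg/mL: all 25 G2 and mitosis genes (adjusted p of the list = 4e-28, 25 alone), with PLK1 at -0.97 and MKI67 at -0.94, and 23 of 25 DNA replication genes, with 1 higher (1.18e-17, 23 and 1 alone, with MCM10 -0.67). Lipid synthesis fell too, with 21 lower and 1 higher of 26 cholesterol genes (4.2e-10, 22 and 1 alone, with HMGCS1 -0.78, SQLE -0.60) and 13 lower and 1 higher of 16 fatty acid synthesis genes (2.46e-07, with GPAM -1.12). All 8 metallothionein and zinc genes fell (7.54e-14, with MT1F -4.01, MT1E -3.29), as did 14 of 16 heat shock genes (5.55e-08, with HSP90AA1 -0.56). Among fatty acid oxidation genes 8 rose and 4 fell of 17 (0.0213), lost at adjusted p = 0.078 with an estimated correlation; VNN1 rose by 2.03 and PLIN2 by 1.24. For p53 targets the list adjusted p of 0.0317 became adjusted p = 0.133 with an estimated correlation, while GDF15 rose by 2.05. HMOX1 changed by -0.29 ± 0.06 (adjusted p = 0.00014) and ALB by 0.17 ± 0.05 (0.0027).

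Between 500 and 20 µg/mL of Menthae Herba IGFBP1 differed by 3.35, CYP1A1 by 3.08 ± 0.07, HAMP by -5.18 and MT1G by -3.93, with 5346 genes called, 2711 higher and 2635 lower. All 25 G2 and mitosis genes were lower (adjusted p of the list = 3.82e-31), and 18 of 20 glycolysis genes higher (8.22e-16). PXR and CAR targets, the drug metabolism list, had 3 higher and 1 lower of 6 (0.0126, 4 and 1 alone). The p53 target list passed here with 10 higher and 1 lower of 23 (0.00303). All libraries of this comparison are in the lower class.

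At 100 µg/mL Menthae Herba raised IGFBP1 by 2.17 ± 0.23 to 119 ± 10.6 CPM and the lipocalin LCN15 by 2.68 ± 0.22, and MT1G changed by -2.34 ± 0.16 to 11.8 CPM. CYP1A1 rose by 0.37 (adjusted p = 9e-04) at 100 and was not called at 20 µg/mL (0.08, 0.62). Glycolysis genes rose at both doses, 18 of 20 at 100 (1.17e-25) and 15 of 20 at 20 µg/mL (2.13e-14). At 100 µg/mL 2337 genes were called, and 1011 without vehicle replicate 1, 1537 without Menthae Herba 100 replicate 1 and 1381 without Menthae Herba 100 replicate 2. At 20 µg/mL 1136 were called, and 118 without vehicle replicate 1, 443 without Menthae Herba 20 replicate 1 and 739 without Menthae Herba 20 replicate 2. A fit with only the groups compared called 244 at 20 µg/mL, among them 18.9% of the 1136, and one with the class as covariate 1708.

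Saposhnikoviae Radix, a root rich in chromones and coumarins, at 500 µg/mL raised CYP1A1 by 3.36 ± 0.07 (adjusted p = 7.7e-40) to 80.0 ± 4.01 CPM, and the NRF2 and AHR genes ALDH3A1 by 1.66, AKR1B10 by 0.86 ± 0.06, AKR1C1 by 0.56 and NQO1 by 0.52. Metallothioneins fell, MT2A by -1.25 ± 0.16, MT1G by -1.13 ± 0.15 and MT1F by -1.05, HAMP changed by -0.74 and TNS4, a focal adhesion gene (chr17 40475828 to 40501597), by -0.74. The comparison (n = 3 and 3) called 966 genes, 497 higher and 469 lower, with 377 in a fit with only the 6 libraries, and the count was 326 without vehicle replicate 1 and 391 without Saposhnikoviae Radix 500 replicate 3. All its libraries are in the lower class.

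By list, Saposhnikoviae Radix at 500 µg/mL raised 14 of 26 NRF2 targets (adjusted p = 7.47e-21, 15 higher and 1 lower alone), 4 of 6 AHR targets (1.92e-13, 4 alone), 5 of 13 gluconeogenesis genes (6.9e-05, 6 alone, with G6PC1 1.10, PCK1 0.61) and 4 of 17 fatty acid oxidation genes (0.00183, 6 alone). Bile acid genes passed with 2 of 14 higher (0.00765, 3 alone). It lowered 6 of 8 metallothionein and zinc genes (2.85e-15, 7 alone), 6 of 26 cholesterol genes (3.77e-07, 7 alone, with SC5D -0.35, HMGCS1 -0.28) and 4 of 21 ATF4 targets, with 1 higher (0.00243, 5 and 1 alone, with NUPR1 -0.56, ASNS -0.46). Fatty acid synthesis (0.000299) was lost at adjusted p = 0.131 with an estimated correlation, and the hypoxia list (0.00664) at adjusted p = 0.294 with an estimated correlation.

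Between 500 and 20 µg/mL of Saposhnikoviae Radix CYP1A1 differed by 2.54 ± 0.06 (adjusted p = 1.1e-35), AKR1B10 by 0.60 and MT1F by -1.03. NRF2 targets had 7 of 26 higher (list adjusted p = 1.32e-23, 16 alone), metallothioneins 6 of 8 lower (1.6e-26, 7 alone), cholesterol genes 3 of 26 lower (5.13e-24, 16 alone) and ATF4 targets 2 of 21 lower (1.13e-10, 8 alone). In this comparison 66 genes were called, 35 higher and 31 lower. A fit with only the groups compared called 30, DESeq2 100, a replicate block within the first code number 107 and a fit without a filter 191. Without 1 library the count was 38 (20 replicate 1), 34 (500 replicate 2), 42 (20 replicate 2), 33 (500 replicate 3) or 40 (20 replicate 3).

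CYP1A1 followed the dose of Saposhnikoviae Radix, at 1.69 (adjusted p = 1.9e-24; 25.1 ± 1.34 CPM) with 100 and 0.82 (2.1e-10; 13.7 CPM) with 20 µg/mL. ALB rose by 0.21 (0.0051) at 20 µg/mL. AHR targets passed at both doses, with 4 of 6 higher at 100 (1.29e-06) and 3 of 6 at 20 µg/mL (0.00131). The 100 µg/mL group had 910 genes called, and the count was 117 without vehicle replicate 1, 395 without Saposhnikoviae Radix 100 replicate 1, 339 without replicate 2 and 284 without replicate 3. The 20 µg/mL group had 1196, and the count was 267 without vehicle replicate 1, 354 without Saposhnikoviae Radix 20 replicate 1, 584 without replicate 2 and 628 without replicate 3.

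Saengmaek-san, a formula that contains ginseng, at 500 µg/mL raised the hypoxia and glucose genes CA9 by 3.02 ± 0.49, IGFBP1 by 2.48 ± 0.23 (adjusted p = 3.4e-10) to 148 ± 21.2 CPM, G6PC1 by 2.04 ± 0.21 and LOX by 1.54. CYP1A1 rose by 0.68 ± 0.08 (5.5e-09) to 12.4 CPM, while AKR1B10 rose by 0.96. MT1G changed by -2.50 ± 0.16 (1.8e-14), MT1F by -2.22, MT1X by -1.99 and MT2A (chr16 56608199 to 56609497) by -1.83. The comparison (n = 3 and 3) called 2105 genes, 943 higher and 1162 lower. A fit with only the 6 libraries called 960, among them 44.1% of the 2105, and the lower class alone (2 and 3 libraries) 2150.

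Saengmaek-san at 500 µg/mL raised 18 of 20 glycolysis genes (list adjusted p = 5.79e-28, 19 alone, with PFKFB4 1.02, PGK1 0.69), 15 of 19 hypoxia genes (4.84e-20, 15 alone), 6 of 13 gluconeogenesis genes (2.17e-06, 6 alone), 15 of 26 NRF2 targets with 2 lower (6.55e-14, 16 and 2 alone, with ABCC2 0.55) and 2 of 6 AHR targets (0.00535, 3 alone). It lowered all 8 metallothionein and zinc genes (4.1e-25), 11 of 26 cholesterol genes (5.7e-11, 16 alone, with HMGCS1 -0.39), 8 of 16 fatty acid synthesis genes (1.16e-07, 9 alone, with ACSS2 -0.41) and 6 of 16 heat shock genes (2.95e-05, 6 alone, with HSPA1A -0.52). All 13 mitochondrially encoded mRNAs were lower than in vehicle (5.22e-12, with MT-ATP8 -0.98, MT-ND2 -0.85), but the mitochondrial share was already lower with 20 µg/mL of Saengmaek-san, 10.9 to 11.7% in its 3 libraries against 13.015 to 16.418% in vehicle. Between 500 and 20 µg/mL the list call (4.53e-05) was lost at adjusted p = 0.256 with an estimated correlation.

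Between 500 and 20 µg/mL of Saengmaek-san metallothioneins were lower, MT1G at -2.49 (adjusted p = 3.4e-14) and MT1F at -2.30, with all 8 genes of the list lower (1.06e-45). AKR1B10 and the zinc transporter SLC39A10 were each higher by 0.89 and CYP1A1 by 0.68. Cholesterol genes were lower for 16 of 26 (6.79e-27, 21 alone) and fatty acid synthesis genes for 5 of 16 (1.83e-14, 13 alone), while glycolysis genes were higher for 11 of 20 (3.33e-17, 12 alone). Acute phase genes passed with 2 of 13 lower (5.28e-05, 5 alone) and immediate early genes with 1 of 16 higher (8.85e-05, 3 alone). The 326 genes called (152 higher, 174 lower) became 176 without Saengmaek-san 500 replicate 1 and 189 without Saengmaek-san 20 replicate 1; with the class as covariate 482 genes were called, among them all 326, but a fit with only the 6 libraries called 55, with 51 of the 326, and the lower class alone (2 and 2 libraries) 168.

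At lower doses of Saengmaek-san CYP1A1 was not called, at -0.04 (adjusted p = 0.83) with 100 and -0.01 (0.98) with 20 µg/mL, yet at 20 µg/mL CA9 rose by 2.69 ± 0.50 (0.0011) and G6PC1 by 1.85 ± 0.22 (1.6e-07). TNS4 changed by -0.60 (8.5e-08) and the AT-hook gene AHDC1 by -0.65 (1.4e-08). Glycolysis genes rose at both doses, 11 of 20 at 100 (2.31e-14) and 9 of 20 at 20 µg/mL (1.87e-14). The 1007 genes called at 100 µg/mL became 299 without vehicle replicate 1 and 282 without Saengmaek-san 100 replicate 2. The 561 at 20 µg/mL became 276 without vehicle replicate 1, 312 without Saengmaek-san 20 replicate 1 and 217 without Saengmaek-san 20 replicate 2. A fit with only the groups compared called 300 at 100 and 216 at 20 µg/mL, and one with the class as covariate 1892 and 1050.

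Guibi-tang, a formula of ginseng, astragalus and other herbs, at 500 µg/mL raised CA9 by 3.13 ± 0.48, CYP1A1 by 2.56 ± 0.07 (adjusted p = 1.1e-33) to 45.8 ± 1.18 CPM, IGFBP1 by 2.52 ± 0.23 and AKR1B10 by 1.41 ± 0.06 (4e-25). The autophagy adaptor SQSTM1, also an NRF2 target, rose by 1.04. MT1G changed by -1.51 ± 0.15 (6e-10), MT1F by -1.46, the transcription factor NFE2 by -0.89 and the ER protein ERP27 by -0.76. The comparison (n = 3 and 3) called 2232 genes, 1114 higher and 1118 lower. A fit with only the 6 libraries called 1698, among them 69.1% of the 2232, and the lower class alone (2 and 3 libraries) 2109.

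NRF2 targets rose with Guibi-tang at 500 µg/mL, 22 of 26 (list adjusted p = 1.46e-30, 23 higher and 1 lower alone, with AKR1C1 0.92, NQO1 0.67), beside 18 of 20 glycolysis genes (1.68e-26, 18 higher and 1 lower alone), 17 of 19 hypoxia genes (2.95e-21, 17 alone, with EGLN3 1.37), 17 of 21 lysosome and autophagy genes with 1 lower (1.4e-14, 19 and 2 alone), 4 of 6 AHR targets (1.51e-08) and 3 of 12 NF-kB and chemokine genes (0.00515, 6 alone, with CCL20 0.71). Fatty acid oxidation passed with 5 higher and 1 lower of 17 (0.00772, with PLIN2 0.83, CPT1A 0.72). ER chaperones fell, 10 of 18 (3.67e-08, 13 alone, with DNAJB9 -0.38, HYOU1 -0.31), as did 16 of 25 G2 and mitosis genes (1.29e-12, 19 alone), 6 of 25 DNA replication genes (4.68e-05, 6 alone), all 8 metallothionein and zinc genes (9.55e-16) and 3 of 4 fibroblast markers (0.000615, with FBN1 -0.54, SPARC -0.42). Heat shock genes (0.00945) were lost at adjusted p = 0.129 with an estimated correlation.

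Between 500 and 20 µg/mL of Guibi-tang CYP1A1 differed by 2.43, AKR1B10 by 1.25, MT1F by -1.71, MT1G by -1.55 and ALB by -0.22 (adjusted p = 7e-04). Secreted liver proteins were lower for 12 of 27 (5.54e-13, 16 alone), the list of plasma proteins made by hepatocytes. NRF2 targets were higher for 20 of 26 (3.58e-34, 20 alone), lysosome and autophagy genes for 17 of 21 (3.6e-17), YAP and actin targets for 7 of 15 with 1 lower (2.54e-06, 9 and 1 alone), and 7 of 18 ER chaperones were lower (1.47e-06, 8 alone). The 1352 genes called (820 higher, 532 lower) became 888 without Guibi-tang 500 replicate 2; with the class as covariate 1525 genes were called, among them 1246 of the 1352, and a fit with only the 6 libraries called 855, with 809 of the 1352.

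At 100 µg/mL Guibi-tang raised IGFBP1 by 1.42 ± 0.24 (adjusted p = 0.00013), SPAG4 by 1.24 and CYP1A1 by 0.72 (8.9e-09), and lowered AHDC1 (-0.73). With 20 µg/mL G6PC1 rose by 1.85 (1.3e-07), AHDC1 changed by -0.70 and CYP1A1 was not called (0.13, 0.44). Hypoxia genes rose at both doses, 9 of 19 at 100 (9.96e-13) and 10 of 19 at 20 µg/mL (1.87e-14). The 1325 genes called at 100 µg/mL became 810 without vehicle replicate 3 and 406 without Guibi-tang 100 replicate 2. With the class as covariate 1412 genes were called, among them 850 of the 1325, and with only the 6 libraries 200. The 729 at 20 µg/mL became 349 without vehicle replicate 2, 409 without vehicle replicate 3, 285 without Guibi-tang 20 replicate 2 and 264 without Guibi-tang 20 replicate 3, and with the class as covariate 783 were called, among them 401 of the 729, and with only the 6 libraries 223.

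Soyo-san, a formula that contains Menthae Herba, at 500 µg/mL raised CYP1A1 by 3.66 ± 0.07 (adjusted p = 1.3e-41), G6PC1 by 2.11, IGFBP1 by 2.05 ± 0.23 to 109 ± 13.7 CPM, ALDH3A1 by 1.74, the membrane repair gene MYOF (chr10 93306429 to 93482317) by 1.62 and the pantetheinase VNN1 (chr6 132681590 to 132714049) by 1.58. HAMP changed by -2.63 ± 0.15 (2.6e-17) to 4.19 CPM, MT1G by -2.34 ± 0.16, MT1F by -2.03 and the kininogen KNG1 by -1.09. The comparison (n = 3 and 3) called 3581 genes, 1687 higher and 1894 lower. Vehicle lies in the lower class and Soyo-san in the higher one; with the class as covariate 3358 genes were called, among them 62.1% of the 3581.

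Soyo-san at 500 µg/mL lowered 19 of 26 cholesterol genes (list adjusted p = 6.55e-14, 21 lower and 1 higher alone, with MVD -0.48, LSS -0.44), 11 of 16 fatty acid synthesis genes (1.17e-12, 12 alone, with ACSS2 -0.62, FASN -0.60), 14 of 25 G2 and mitosis genes (2.13e-12, 19 alone, with PLK1 -0.46), 14 of 25 DNA replication genes (2.27e-05, 15 lower and 2 higher alone), 8 of 16 heat shock genes (9.33e-06, 9 alone) and 7 of 8 metallothionein and zinc genes (4.37e-16, 8 alone). It raised 14 of 26 NRF2 targets with 3 lower (2.27e-06, 15 and 3 alone), 4 of 6 AHR targets with 1 lower (3.85e-06), 11 of 20 glycolysis genes (3.11e-09, 15 alone, with PFKP 0.69), 9 of 19 hypoxia genes (2.84e-07, 13 alone), 7 of 13 gluconeogenesis genes (2.59e-05, 8 alone) and 7 of 17 fatty acid oxidation genes (0.000178, 7 higher and 1 lower alone, with CPT1A 0.50). The immediate early list (0.000683) was lost at adjusted p = 0.062 with an estimated correlation, while EGR1 rose by 1.01.

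Within the higher class, 500 against 20 µg/mL of Soyo-san gave CYP1A1 at 3.31, MYOF at 1.43, IGFBP1 at 1.37 (adjusted p = 3e-05), HAMP at -2.57, MT1G at -2.29 and MT1F at -2.06. Cholesterol genes were lower for 21 of 26 (1.9e-28, 24 alone), fatty acid synthesis genes for 11 of 16 (3.35e-20, 14 alone) and G2 and mitosis genes for 13 of 25 (3.88e-16, 21 alone). NF-kB and chemokine genes had 4 higher and 1 lower of 12 (0.000151, 7 and 2 alone), and 5 of 15 YAP and actin targets were higher (0.00187, 8 higher and 1 lower alone). In all, 1262 genes were called, 706 higher and 556 lower.

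CYP1A1 rose (adjusted p = 1.1e-21) to 22.0 ± 2.17 CPM with Soyo-san at 100 µg/mL, where AHR targets had 4 of 6 higher (4.14e-05). Heat shock genes had 5 of 16 lower at 100 (9.14e-05) and 5 of 16 at 20 µg/mL (1.11e-05). The 1383 genes called at 100 µg/mL became 828 without vehicle replicate 2, 856 without vehicle replicate 3, 903 without Soyo-san 100 replicate 1 and 428 without Soyo-san 100 replicate 3. The 646 at 20 µg/mL became 309 without vehicle replicate 2, 361 without vehicle replicate 3, 142 without Soyo-san 20 replicate 1 and 378 without Soyo-san 20 replicate 3. With the class as covariate 596 of the 1383 and 235 of the 646 were called as well. A fit with only the groups compared called 877 at 100 and 451 at 20 µg/mL.

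Okbyeongpung-san, a formula that contains Saposhnikoviae Radix, at 500 µg/mL raised CYP1A1 by 2.07 ± 0.07 (adjusted p = 6.1e-29) to 32.6 ± 1.35 CPM, G6PC1 by 1.75, the hypoxia gene NDRG1 by 0.70 ± 0.11, AKR1B10 by 0.53 and NQO1 by 0.41. TNS4 changed by -0.88 ± 0.07, the AP-1 repressor JDP2 by -0.68, and the amino acid stress genes ASNS by -0.52 and SESN2 by -0.50. G6PC1, NDRG1, TNS4 and SESN2 were called in the same direction at 20 µg/mL in all 6 extracts. Their changes are thus not particular to 500 µg/mL and could hold a vehicle difference. Between 500 and 20 µg/mL of Okbyeongpung-san only 4 genes were called. The comparison (n = 3 and 3) called 1517 genes, 702 higher and 815 lower, and the count was 958 without vehicle replicate 2, 966 without vehicle replicate 3, 728 without Okbyeongpung-san 500 replicate 2 and 856 without Okbyeongpung-san 500 replicate 3. Vehicle lies in the lower class and Okbyeongpung-san in the higher one; with the class as covariate 1899 genes were called, among them 52.1% of the 1517.

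By list, Okbyeongpung-san at 500 µg/mL raised 13 of 26 NRF2 targets with 1 lower (adjusted p = 1.62e-12, 17 and 1 alone, with AKR1C2 0.49), 4 of 6 AHR targets (8.55e-08, 4 alone), 8 of 19 hypoxia genes (1.97e-07, 9 alone), 8 of 20 glycolysis genes (1.43e-06, 9 alone, with PGK1 0.44, LDHA 0.30), 4 of 17 fatty acid oxidation genes (6e-05, 4 alone) and 2 of 13 gluconeogenesis genes (0.00307, 3 alone). YAP and actin targets had 5 of 15 lower (1.72e-05, 9 lower and 1 higher alone, with ANKRD1 -0.54, THBS1 -0.30). Calls lost with an estimated correlation were metallothioneins (0.000826; adjusted p = 0.112 with an estimated correlation), nuclear oxidative phosphorylation genes (6.13e-06; adjusted p = 0.175 with an estimated correlation), ribosomal proteins (0.000184; adjusted p = 0.486 with an estimated correlation) and mitochondrially encoded mRNAs (1.51e-08; adjusted p = 0.102 with an estimated correlation).

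The genes CYP1A1 (1.79 ± 0.07, adjusted p = 2.4e-26), AKR1B10 (0.42 ± 0.06, 4.2e-05) and AKR1C2 (0.38 ± 0.05, 2.6e-05) were higher and ASNS (-0.41 ± 0.07, 0.00051) lower at 500 than at 20 µg/mL of Okbyeongpung-san, 4 genes against 776 by unadjusted p under 0.05. AKR1C2 was not called in a fit with only the 6 libraries (0.0915). By list, NRF2 targets were higher (9.92e-17, 2 of 26 called, 7 higher and 1 lower alone) and AHR targets too (3.36e-13, 1 of 6 called, 3 alone). Fatty acid synthesis (4.09e-14), cholesterol (3.74e-06) and metallothionein genes (5.75e-07) were lower as lists with 0 members called, and with 6, 0 and 4 alone. ATF4 targets were lower with 1 of 21 called (8.88e-07, 2 alone).

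CYP1A1 rose by 0.68 (adjusted p = 8.4e-08) to 12.4 CPM with Okbyeongpung-san at 100 µg/mL, where AHR targets had 3 of 6 higher (0.00635) and YAP and actin targets 5 of 15 lower (0.00034). Heat shock genes had 5 of 16 lower at 20 µg/mL (1.6e-05). The 2154 genes called at 100 µg/mL became 1381 without vehicle replicate 2, 1388 without Okbyeongpung-san 100 replicate 2 and 1095 without Okbyeongpung-san 100 replicate 3. The 1164 at 20 µg/mL became 634 without vehicle replicate 2 and 356 without Okbyeongpung-san 20 replicate 3. A fit with only the groups compared called 1232 at 100 and 273 at 20 µg/mL. With the class as covariate 1206 of the 2154 and 594 of the 1164 were called as well.

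HCAR3, a receptor for hydroxylated fatty acids, G6PC1, PFKFB4, NDRG1 and LCN15 were higher and TNS4, AHDC1 and SESN2 lower than vehicle at 20 µg/mL in all 6 extracts, among 38 higher and 67 lower genes, and were chosen from these after their values were seen. The mean log2 fold change was 1.09 for LCN15, -0.59 for TNS4 and -0.59 for AHDC1. With the library class as covariate 66 of the 105 genes were called in all 6. If the extracts were independent, 2.7e-06 higher and 8.9e-06 lower genes would be called in all 6, but the comparisons use the same 3 vehicle libraries. In simulated counts with unchanged groups and 1 vehicle in common, 0 genes were called in all 6. The correlation of fold changes, averaged over pairs of extracts, was 0.478 to 0.535 in 5 draws. Simulated vehicle libraries were drawn like all others, so the simulation does not cover vehicle libraries that lie apart. The vehicle libraries enter all 6 comparisons and at n = 3 cannot be halved, so the excess is not corrected for them. Without vehicle replicate 1 the calls at 20 µg/mL fell from 1136 to 118 with Menthae Herba and from 1196 to 267 with Saposhnikoviae Radix. Without it they fell from 561 to 276 with Saengmaek-san and from 646 to 488 with Soyo-san. Without vehicle replicate 2 they fell from 729 to 349 with Guibi-tang and from 1164 to 634 with Okbyeongpung-san. Without vehicle replicate 3 Menthae Herba had 1224. Fits without some extract libraries fell too. The genes called in all 6 were not recounted. The amount of DMSO in the extract groups is not given in the sources used here, so a difference in DMSO would enter all 6 comparisons as well.

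Soyo-san and its constituent Menthae Herba moved IGFBP1, HAMP and metallothioneins in the same direction from 20 to 500 µg/mL, groups with no library in common. Genes higher in both numbered 648 against 115 expected if independent, and genes lower in both 489 against 88. Menthae Herba also shared 520 higher (134 expected) and 317 lower genes (84.2) with Guibi-tang, and 132 (24.8) and 140 (27.5) with Saengmaek-san, so a large overlap is not particular to Soyo-san. Across all tested genes the log2 fold changes correlated at Pearson 0.28 and Spearman 0.457, and across 9334 genes with a mean of at least 10 CPM at 0.78 and 0.676; Pearson values over the same 9334 genes were 0.575 with Saengmaek-san and 0.474 with Guibi-tang. For Okbyeongpung-san and Saposhnikoviae Radix the correlations were 0.023 and 0.043, with CYP1A1 and AKR1B10 among the 3 genes higher in both (0.00631 expected). Each of these correlations describes genes, which are not replicates, so no p-value is given.

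Soshiho-tang has 1 library per dose, so no test was made and no gene is called. CYP1A1 had the largest log2 ratio of 500 over 20 µg/mL, 3.56, at 881, 259 and 74.6 CPM with 500, 100 and 20 µg/mL. AQP3 stood at 2.21, IGFBP1 at 1.43 and AKR1B10 at 1.38, and HAMP at -1.54, MT1G at -1.24 and MT1E at -1.09; HMOX1 stood at 0.55 and ALB at -0.16. List medians of the same ratio were 1.19 for AHR targets, 0.506 for NRF2 targets, 0.18 for glycolysis, -0.948 for metallothioneins and -0.207 for G2 and mitosis. All 5 lie outside the range of 10000 random lists of matched expression, but the genes of a list vary together between any 2 libraries, so this is no evidence of a dose effect. All 3 libraries lie in the higher class.

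Interferon-stimulated genes and leukocyte markers passed in none of the 6 extracts, neither against vehicle at 500 µg/mL nor against 20 µg/mL. Replication-dependent histones, whose mRNAs lack a poly-A tail, passed in none at 500 against 20 µg/mL. Against vehicle they passed for Saposhnikoviae Radix alone (adjusted p = 0.0468; 2 of 10 lower; adjusted p = 0.112 with an estimated correlation), at 0.214 without vehicle replicate 2, 0.098 without Saposhnikoviae Radix 500 replicate 2 and 0.0653 without Saposhnikoviae Radix 500 replicate 3. The lung and neural list had 2 expressed members, TUBB3 and SYP, and was not tested. CYP3A4 was too low to test, with 9 counts (0.356 CPM) in the highest library, and HMOX1 was not called with Saengmaek-san (0.04, 0.78) or Soyo-san (-0.05, 0.64) at 500 µg/mL.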

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

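All tests in this part were chosen after seeing the data. The change from 20 to 500 µg/mL of Soyo-san differed from that of its constituent Menthae Herba in 1094 genes (502 higher, 592 lower in Soyo-san minus Menthae Herba; 3165 by unadjusted p), with edgeR's quasi-likelihood interaction test. IGFBP1 differed by -1.99 ± 0.31 (adjusted p = 1.8e-05), HAMP by 2.61 ± 0.30 (4.2e-08) and MT1G by 1.64 ± 0.28 (8.9e-05), so each moved less in Soyo-san. CYP1A1 (0.23 ± 0.10, 0.17) and MYOF (-0.06 ± 0.21, 0.92) were not called. The doses are of whole extracts and Menthae Herba is a part of Soyo-san, so equal doses do not hold equal amounts of the herb. The smaller changes of IGFBP1, HAMP and MT1G are therefore no measure of how the formula alters the effect of the herb.

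With labels of the libraries split 50 ways in fits of the 4 groups, the real split called 1370 genes, 2 of 50 splits, the real one included, called as many, and the highest other called 1902. The 4 other splits that kept the 500 µg/mL libraries of each extract together and mixed those at 20 µg/mL called 1271, 1902, 1023 and 924 genes, and the rest 0 or 1. All Menthae Herba libraries are in the lower class and all Soyo-san libraries in the higher one, so these splits set class against class at 500 µg/mL, a difference that cancels in the real comparison. With the class as covariate in each split where it can be estimated, the 4 called 1449, 439, 1178 and 898 genes, the highest count of the rest was 931, and again 2 of 50 splits, the real one included, called as many as 1370. In both sets the share is under 0.05. Splits that mix the extracts at 500 µg/mL put the difference between extracts into the spread within groups. Without the covariate such splits called 0 or 1, so the share partly reflects how the splits were made. A random grouping is therefore not excluded by it. Class and extract are the same division in these 12 libraries, so the covariate takes out both.

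The change from 20 to 500 µg/mL of Okbyeongpung-san differed from that of its constituent Saposhnikoviae Radix in 3 genes (1 higher, 2 lower; 651 by unadjusted p): CYP1A1 by -0.75 ± 0.10 (adjusted p = 4.2e-06), TFRC by 0.47 ± 0.09 (0.031) and LY6G5B by -0.85 ± 0.16 (0.017). The count was 1 without Saposhnikoviae Radix 20 replicate 1, without Saposhnikoviae Radix 500 replicate 2, without Saposhnikoviae Radix 20 replicate 2, without Okbyeongpung-san 500 replicate 1 and without Okbyeongpung-san 20 replicate 2. In fits of the 4 groups the real split called 1 gene, 7 of 50 splits, the real one included, called as many, and the highest other called 393. The 4 other splits that kept the 500 µg/mL libraries of each extract together called 57, 393, 0 and 0 genes. Saposhnikoviae Radix is in the lower class and Okbyeongpung-san in the higher one, so these counts carry a class difference that cancels in the real comparison, and with the class as covariate the 4 called 1, 0, 2 and 0. In that set 12 of 50 splits, the real one included, called as many as the real 1, with 2 as the highest other. A random grouping cannot be excluded for this count in either set. The doses are of whole extracts, so equal doses do not hold equal amounts of Saposhnikoviae Radix here either. TFRC and LY6G5B were chosen after their values were seen, and 3 genes were also called with the library class as covariate.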

How the results depend on the processing

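The fits with the library class and the interaction tests were chosen after seeing the data. With RLE scaling every count of genes called lay within a factor of 1.5, and all 360 list tests kept direction and side of the threshold. Without a filter, 500 against 20 µg/mL gave 191 genes for Saposhnikoviae Radix, 536 for Saengmaek-san and 108 for Okbyeongpung-san, and the Okbyeongpung-san minus Saposhnikoviae Radix interaction 118. DESeq2 gave 100 for Saposhnikoviae Radix 500 against 20 µg/mL.

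A fit with only the groups compared gave 377 (Saposhnikoviae Radix) and 960 (Saengmaek-san) at 500 µg/mL against vehicle. At 100 µg/mL it gave 300 (Saengmaek-san), 200 (Guibi-tang), 877 (Soyo-san) and 1232 (Okbyeongpung-san), and at 20 µg/mL 244 (Menthae Herba), 216 (Saengmaek-san), 223 (Guibi-tang) and 273 (Okbyeongpung-san). For 500 against 20 µg/mL it gave 30 (Saposhnikoviae Radix), 55 (Saengmaek-san) and 855 (Guibi-tang), and 1 for the Okbyeongpung-san minus Saposhnikoviae Radix interaction. The cause was not tested.

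With the library class as covariate the counts were 1534 for Saposhnikoviae Radix at 500 µg/mL against vehicle, 1448 for Saposhnikoviae Radix and 1892 for Saengmaek-san at 100, and 1708 for Menthae Herba, 1050 for Saengmaek-san and 1752 for Okbyeongpung-san at 20 µg/mL. Okbyeongpung-san 500 against 20 µg/mL gave 9. The sign of 7SK, a small nuclear RNA with many copies, reversed for Soyo-san at 500 (adjusted p = 0.766) and Okbyeongpung-san at 100 µg/mL against vehicle (adjusted p = 0.986). Within the lower class Guibi-tang gave 176 at 100 and 55 at 20 µg/mL against vehicle, and 500 against 20 µg/mL gave 168 for Saengmaek-san and 417 for Guibi-tang. Within the higher class these were 30 and 407. All of these but the 168 rest on an arm of 1 library, and for 30 both arms, with the lone library assumed to vary like the other groups; counts from fewer libraries are no test of the class.

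The replicate block as a factor over all groups moved no count by a factor of 1.5. A replicate block within the first code number gave 107 for Saposhnikoviae Radix, 501 for Saengmaek-san and 9 for Okbyeongpung-san at 500 against 20 µg/mL. Only in Soyo-san 500 µg/mL against vehicle did all 3 libraries correlate best with the vehicle library of their own number, so the numbers were not taken to pair libraries across groups. In Saengmaek-san and Guibi-tang, however, all 6 libraries numbered 1 lay in the lower class and all 6 numbered 3 in the higher one.

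Leaving out 1 library at a time, the lowest and highest counts at 500 µg/mL against vehicle were 5707 and 6149 for Menthae Herba, 326 and 911 for Saposhnikoviae Radix, 1546 and 1891 for Saengmaek-san, 1662 and 1835 for Guibi-tang, 2683 and 3179 for Soyo-san, and 728 and 1067 for Okbyeongpung-san. At 100 µg/mL they were 1011 and 2217, 117 and 898, 282 and 992, 406 and 1463, 428 and 1372, and 1095 and 2110 in the same order. At 20 µg/mL they were 118 and 1224, 267 and 1092, 217 and 445, 264 and 855, 142 and 488, and 356 and 1049. For 500 against 20 µg/mL they were 4458 and 4993, 33 and 89, 176 and 288, 888 and 1252, 887 and 1004, and 4 and 6. The interaction counts ran from 822 to 1045 for Soyo-san minus Menthae Herba and from 1 to 4 for Okbyeongpung-san minus Saposhnikoviae Radix. The direction of the ribosomal protein list at 500 against 20 µg/mL of Saengmaek-san reversed without Saengmaek-san 500 replicate 1 (adjusted p = 0.0979). Its adjusted p ran from 0.000225 without Saengmaek-san 500 replicate 3 to 0.346 without Saengmaek-san 20 replicate 1.

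Of 518 tests of named genes the fit with only the groups compared made 83 weaker. Over all fits without 1 library 2690 tests of named genes stayed the same, 427 were weaker and 3 stronger. The class as covariate left 485 the same, with 30 weaker and 3 stronger. RLE scaling made 5 weaker, no filter 20, and DESeq2 4 weaker and 2 stronger. Of 360 list tests the estimated correlation made 65 weaker. Over all fits without 1 library 2039 list tests stayed the same, 69 were weaker, 51 stronger and 1 reversed. The weaker ones were most for Okbyeongpung-san at 500 against 20 µg/mL, 18 tests over 8 lists. Without a filter 20 list tests were stronger and 7 weaker, and with the library class as covariate 6 were stronger and 7 weaker. The correlation of Menthae Herba with Soyo-san rose from 0.28 to 0.78 with a mean of at least 10 CPM.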

Other observations

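TUBB1, a beta tubulin of platelets, rose at 500 µg/mL against vehicle by 2.27 ± 0.22 with Menthae Herba (adjusted p = 7.5e-12), 1.54 ± 0.23 with Saengmaek-san (3.8e-06) and 1.38 ± 0.23 with Guibi-tang (1.8e-05). SPAG4, a nuclear envelope gene, rose by 1.47 ± 0.22 with Saengmaek-san, 1.54 ± 0.22 with Guibi-tang and 1.21 ± 0.23 with Soyo-san. The sulfotransferase CHST15 (2.17 ± 0.11) and the FOXO target DEPP1 (2.16 ± 0.14) rose with Menthae Herba, and CD109 (1.08 ± 0.09) and the growth factor AREG (1.07 ± 0.11) with Soyo-san. The test of the class for the genes called at 20 µg/mL, the class test for metallothioneins in Guibi-tang and the tests of summed metallothionein CPM by extract were chosen after seeing the data.

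Genes called at 20 µg/mL against vehicle in every extract (38 higher, 67 lower, G6PC1 and TNS4 among them) were weighed against 3 explanations. Genes called in each of the 4 extracts with higher-class libraries were followed in Menthae Herba, whose libraries all share the class of vehicle. Their median change there was 0.796 times that in the 4, and the class cannot make a change in Menthae Herba. The choice favoured genes that do not follow the class, since Saengmaek-san and Guibi-tang mix the classes, and used the same vehicle libraries. The ratio therefore does not decide on the class in the 4. With the class as covariate 66 of the 105 genes were called in all 6. Vehicle libraries apart from all others would leave the genes unmoved by dose, and an effect that grew with dose would move most further. In held-out extracts the ratio of the 500 against 20 µg/mL change to the 20 µg/mL change had a median of 0.126 and a median of 67.3% of the genes moved further, but the extracts went opposite ways, from -0.195 and 23.9% with Saposhnikoviae Radix to 0.752 and 76.3% with Menthae Herba. Vehicle libraries also had a higher mean mitochondrial share, 14.32%, than the libraries of each first code number of the extracts, 9.8463 to 11.8645%. Replicate 1 raised the vehicle mean at 16.418%, with replicates 2 and 3 at 13.015 and 13.527%. Single extract libraries reached 14.315% (Guibi-tang 20 µg/mL replicate 1) and 14.274% (Menthae Herba 20 µg/mL replicate 3), so the ranges overlap. The higher mean goes with vehicle libraries that lie apart, but the overlap limits its weight. Both explanations stay open, and the genes could hold a vehicle difference as well as an effect common to the extracts.

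Libraries of 1 group in 2 classes by MALAT1 level were weighed as GC content and transcript length, and no biological explanation was tested. They occur in 6 replicated groups, all of Saengmaek-san or Guibi-tang, and the class difference of genes is estimated within these groups alone. It correlated with GC content of the longest transcript at -0.701 (Spearman), so the class difference goes with GC content. This correlation does not tell a difference in library preparation from one in the RNA of the cells. The correlation with transcript length was 0.112 and turned to -0.141 at given GC content, against -0.704 for GC content at given length, which leaves a small part of length open. The labels do not record a preparation batch, so what made the classes is not known here.

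Metallothionein mRNAs lower at 500 than at 20 µg/mL in every extract were weighed against 3 technical explanations. Reads moved among the 7 metallothionein genes summed would leave the sum unchanged. Yet in the 5 extracts without Okbyeongpung-san the smallest change of the summed CPM was -0.942 in log2. For Okbyeongpung-san the sum changed by -0.381, from 407 ± 97.8 CPM at 20 to 312 ± 22.8 at 500 µg/mL. That change lay within the SD of the 20 µg/mL group, so shared reads stay open there. The sum does not cover reads moved to genes outside it, in any extract. Loss of short transcripts would lower other short genes. Over 1053 genes with a longest transcript of 396 to 1727 bases the lowest median of any extract was -0.098. A median over this range does not cover a loss limited to the shortest transcripts. The class make-up of the 500 and 20 µg/mL groups differs in Guibi-tang alone, where the list median was -1.202 with the class as covariate. Shared reads in Okbyeongpung-san, reads moved to genes outside the sum and a loss limited to the shortest transcripts stay open. Apart from these, the values argue against the 3 explanations. A drop in free zinc or in the activity of the zinc sensor MTF1, or binding of metal ions by the extracts, could lower these mRNAs. No such cause was measured.

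Splits of the 6 libraries of a comparison into 2 groups of 3 gave 10 splits each, too few for a share under 0.05. In all 24 comparisons the real split alone reached its count, 1 of 10. At 500 µg/mL against vehicle the real count and the highest other were 6566 and 0 for Menthae Herba, 377 and 3 for Saposhnikoviae Radix, 960 and 1 for Saengmaek-san, 1698 and 1 for Guibi-tang, 3540 and 1 for Soyo-san, and 1718 and 1 for Okbyeongpung-san. At 100 µg/mL they were 2370 and 0, 1239 and 3, 300 and 4, 200 and 3, 877 and 1, and 1232 and 2 in the same order. At 20 µg/mL they were 244 and 1, 1388 and 1, 216 and 2, 223 and 110, 451 and 2, and 273 and 2. For 500 against 20 µg/mL they were 5075 and 0, 30 and 3, 55 and 2, 855 and 126, 1678 and 1, and 3 and 2. The split of Guibi-tang with 126 genes follows the library classes, and with the class as covariate 1525 genes were called in the real comparison; the one with 110 puts vehicle replicate 1 with Guibi-tang 20 replicates 2 and 3.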
